A study of Mus musculus with 16 samples.

How the data were processed

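Expression was measured by RNA sequencing in 16 libraries, 12 of iPSCs made from mouse embryonic fibroblasts and 4 of EBs formed by the hanging-drop method. Per the labels' protocols, iPSCs were grown on feeders in DMEM with KSR, a serum replacement, and doxycycline was given for 5 to 7 days. PolyA RNA was fragmented and made into strand-marked (dUTP) TruSeq libraries, which were sequenced on a HiSeq2500. Per the submitters' processing notes, the tools were FastQC, TopHat2 2.0.10, Bowtie 1.0.0, SAMtools 0.1.19 and Cufflinks 2.2.1, with the mouse build GRCm38 (mm10). The notes give no settings and no annotation version in the sources used here.

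The authors deposited 1 table of FPKM values (fragments scaled to transcript length and library size) with 23284 genes and a column for each library, all of which matched a title. FPKM is scaled to library size and gene length, so a transcript that takes a larger share lowers the rest, and an exact 0 can be a failed estimate as well as an absent transcript. Reads shared between near-identical genes, such as ribosomal protein genes and their pseudogenes, can be split unevenly by the estimate. Of the genes, 2781 were at 0 in every library and 5010 to 5437 in a single library. The sequencing depth is unknown. The spacing of low FPKM values gave relative depths of 0.873 to 1.14, but only 50.9% of 34278 low values over 3231 genes lay within 0.1 of a whole unit. Whole reads were therefore not recovered, no count model was used, and no counting interval or floor can be given.

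The titles gave the groups, and the choice of tests, lists, named genes and alternatives was made before the data were examined unless stated otherwise. Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a trend, two-sided, Benjamini-Hochberg adjustment at 0.05), over genes with at least 1 FPKM in at least 2 libraries of the fit. Groups of a letter with a number or EB had their own means and shared 1 estimate of the spread, over 16 libraries for comparisons with EBs and for KIX against KI and over 12 otherwise. The comparisons were EB against iPSC, each pair of numbers, D against V in iPSCs, at each number and in EBs. Also compared were the change of that difference between EBs and iPSCs and between numbers 10 and 1, and KIX against KI with the groups held constant. KIX against KI at each number and in EBs, and the change of that difference from number 1 to 4 and from 4 to 10, were added after the data were seen, with prefix by number means and D and V as 2 replicates.

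The prefix gives libraries of different groups the same replicate number. Within a number or EB, the deviations of D and V libraries of the same prefix from their group means correlated across genes with r from 0.207 to 0.379, so the prefix pairs the libraries in comparisons of D with V. Between numbers the r ranged from -0.130 to 0.243, which overlaps that range, and no pairing by prefix was taken there. As libraries of the same prefix and number deviate together, the 4 libraries of a number or of EBs are not independent. Comparisons between numbers and of EBs with iPSCs treat them as if they were, so their p-values can be too small. Fits by letter and number also count the difference between KI and KIX as spread, so p-values can instead be too large. This bears most on D against V, whose pairing by prefix those fits leave out.

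There were 22 gene lists: general pluripotency, naive pluripotency, primed or formative epiblast, 2-cell-like state, DNA methylation machinery, neuroectoderm, primitive streak and early mesoderm, cardiac muscle, definitive endoderm and liver-type, extraembryonic endoderm, blood and endothelium, trophoblast, germ line, fibroblast (feeder type), imprinted, cell cycle, p53 and stress, glycolysis, reported miR-203 targets, sex chromosome checks, reference and Hox clusters. Lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The fibroblast score is the mean of log2(FPKM + 1) over the 10 fibroblast genes. Dnmt3a and Dnmt3b stand in both the methylation and the target list.

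Named genes are, for each comparison, the 6 largest rises and the 6 largest falls among called genes whose libraries do not overlap between the sides (no such condition for changes of a difference), leaving out predicted or unnamed models and microRNA and small nucleolar RNA genes. To these were added up to 4 called genes of each list with the largest change or, where none was called, the 2 with the highest mean, and always Pou5f1, Nanog, Sox2, Dnmt3a, Dnmt3b and Mir203. Named genes may be left out for comparisons other than EB against iPSC, number 10 against 1 and D against V. Names outside the rule are Mir26b, Mir3061, Mir705, Mir302a, Mir409, Snord95, Car4, Fgd1, Fgfbp1, Foxj1, Mogat2, Psors1c2, Slc39a4, Steap3, Dnmt3l, Klf4, Lef1, Ldha and the genes named for the change of the KIX minus KI difference, which were chosen after their values were seen.

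Seed matches were sought in the longest annotated 3′ UTR of each gene in the GRCm38 reference, to which 20911 gene symbols matched directly and 1923 through a synonym, with 450 unmatched. Of these, 19938 had a 3′ UTR. A gene had a site where CATTTCA occurred, and its change was compared with that of genes without a site by limma's camera, with an adjustment over 13 comparisons that was chosen after the data were seen. The difference of medians was ranked among those of 100 shuffled heptamers of the same bases, and for the longer match among 100 shuffled octamers, which were added after the data were seen. The method was tested on simulated data with 200 genes changed by known folds. Of the genes changed 1.5-fold, 2-fold and 4-fold, the model recovered 74.6%, 94.0% and 100% for EB against iPSC, 65.7%, 86.6% and 97.0% for number 10 against 1. The shares were 85.1%, 95.5% and 98.5% for D against V in iPSCs, and 86.6%, 92.5% and 98.5% for KIX against KI at number 4. They were 85.1%, 95.5% and 100% for KIX against KI over all libraries, and 62.7%, 79.1% and 98.5% for its change from number 4 to 10. False calls were, in this order, 6 of 185, 7 of 173, 16 of 202, 12 of 197, 19 of 206 and 6 of 166. Only genes above a minimum mean level were changed, and the noise was independent between libraries, so the pairing by prefix was not simulated.

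Alternatives were a pseudocount of 0.1, no filter and a filter on the mean, median-ratio rescaling, quantile normalization, no trend, library weights, number means alone, all 16 libraries in every fit, EB libraries alone, the prefix or letter as a block, and leaving out each library in turn. Added after the data were seen were prefix by number means and the fibroblast score as a covariate. Other splits of the libraries used simpler models, which called 10664 genes in place of 10960 for EB against iPSC (plain means), 4735, 2306 and 2802 in place of 3588, 1138 and 1544 for number 10 against 1, 4 against 1 and 10 against 4 (number means), and 167 in place of 9 for KIX against KI (number and EB means). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.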

Results

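Polyadenylated RNA was measured in 16 libraries of mouse cells that carry a doxycycline-inducible construct for the microRNA miR-203, listed as the genotype ColA1_miR203; Rosa26rtTA. Of these, 12 came from induced pluripotent stem cells (iPSCs) grown on a layer of feeder cells, and 4 came from embryoid bodies (EBs), the aggregates in which such cells differentiate. The study asked how a short pulse of miR-203 alters the transcriptome over time, sampling before induction, 5 and 20 days after a 5-day induction, and after 7 days as EBs. Library titles join a prefix (KI or KIX), a letter (D or V) and a number (1, 4 or 10) or EB. The labels define none of these and list the same doxycycline treatment for every library, so titles were compared as codes and no treatment or day was assigned to them. Each of the 8 groups of a letter with a number or EB held 2 libraries, replicate 1 with the prefix KI and replicate 2 with KIX. The labels do not say that these are separate cultures, so p-values measure only the spread between these samples. Where the 2 libraries of a group are the replicates, this spread is the difference between KI and KIX. It was wider than that between D and V libraries of the same prefix, so it can hold a real difference between samples. In comparisons of KIX with KI within a number or EBs, the spread is that between D and V, which may be technical. Total expression per library lay between 612598 and 724350 FPKM (fragments scaled to gene length and library size). In each library 12117 to 12501 genes reached 1 FPKM and the 10 most abundant genes took 6.77% to 7.91% of the total. Levels are given as mean ± SD in FPKM, and changes are differences of log2(FPKM + 1), which understates changes of low genes. A gene is said to have risen or fallen only at an adjusted p under 0.05 in limma.

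The annotated gene of the induced microRNA, Mir203, lies on the plus strand of chromosome 12 at 112130880 to 112130955 (GRCm38). FPKM listed under Mir203 may come from this gene or from the inducible construct. At numbers 1 and 4 Mir203 was listed at 0 in all KI libraries. In the KIX libraries it stood at 1868 FPKM in D1, 1969 FPKM in V1, 2254 FPKM in D4 and 1728 FPKM in V4. At number 10 it was listed at 0 in all 4 libraries, and in EBs it stood at 90.1 FPKM in the KI library of V and 212.4 FPKM in the KIX library of D, with 0 in the other two. FPKM divides by gene length, so few fragments give a large value for so short a gene. All KIX libraries of numbers 1 and 4, however, stood far above the 90.1 FPKM listed in EBs, and all KI libraries there at 0. These values argue against stray fragments as the source of that difference between the prefixes. The labels do not say which libraries were induced, so no treatment was assigned from them.

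**Figure D1:**
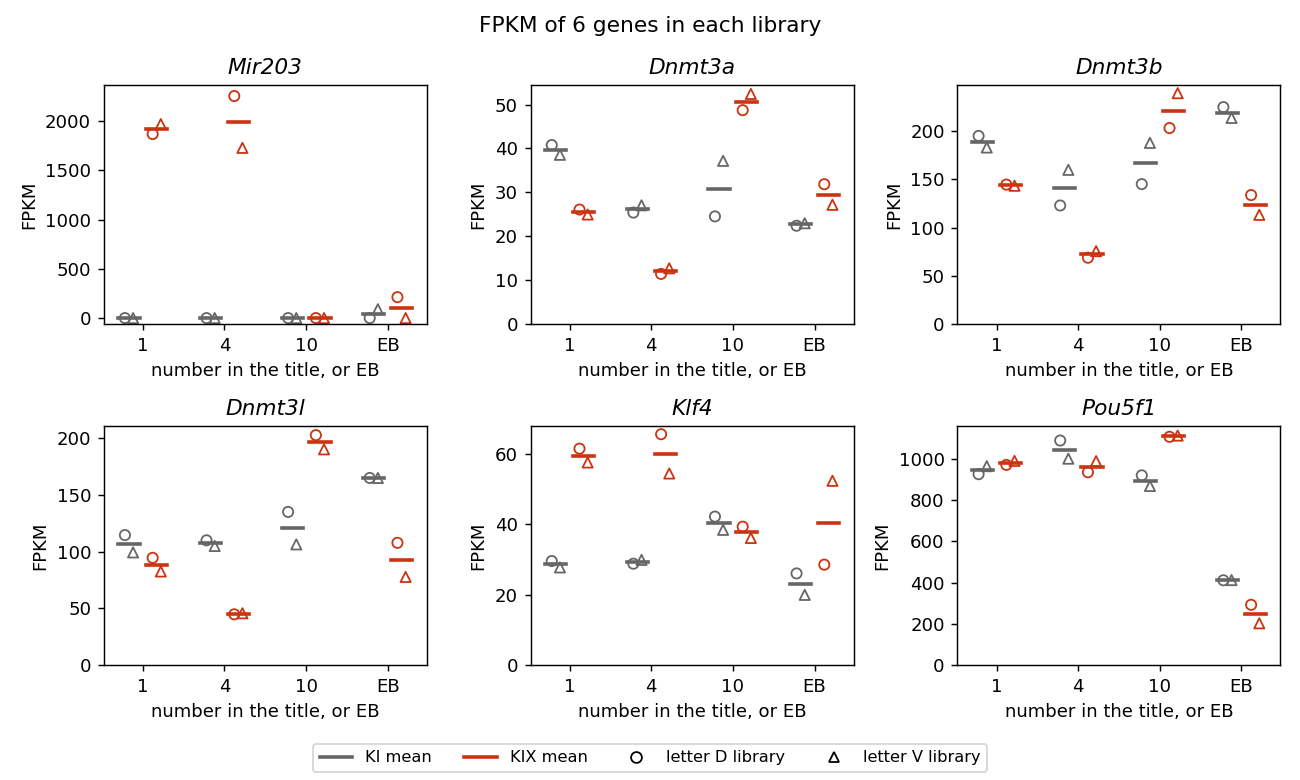
FPKM of Mir203, Dnmt3a, Dnmt3b, Dnmt3l, Klf4 and Pou5f1 in each of the 16 libraries, by number or EB, with KI in grey, KIX in red and lines at the mean of 2 libraries. Mir203 stood between 1728 and 2254 FPKM in the KIX libraries of numbers 1 and 4 and was listed at 0 in the KI libraries of those numbers.

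Libraries of the same prefix and number but different letter were the most alike. Over genes with a mean of at least 50 FPKM, the SD of their log2 difference was 0.111 to 0.341, against 0.240 to 0.473 between KI and KIX libraries of the same letter and number. The first principal component held 63.8% of the variance and placed the EB libraries at 97.4 to 108.8 and the iPSC libraries at -44.3 to -26.5. The second, with 7.09%, placed the libraries of number 10 at -34.9 to -23.7.

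**Figure D2:**
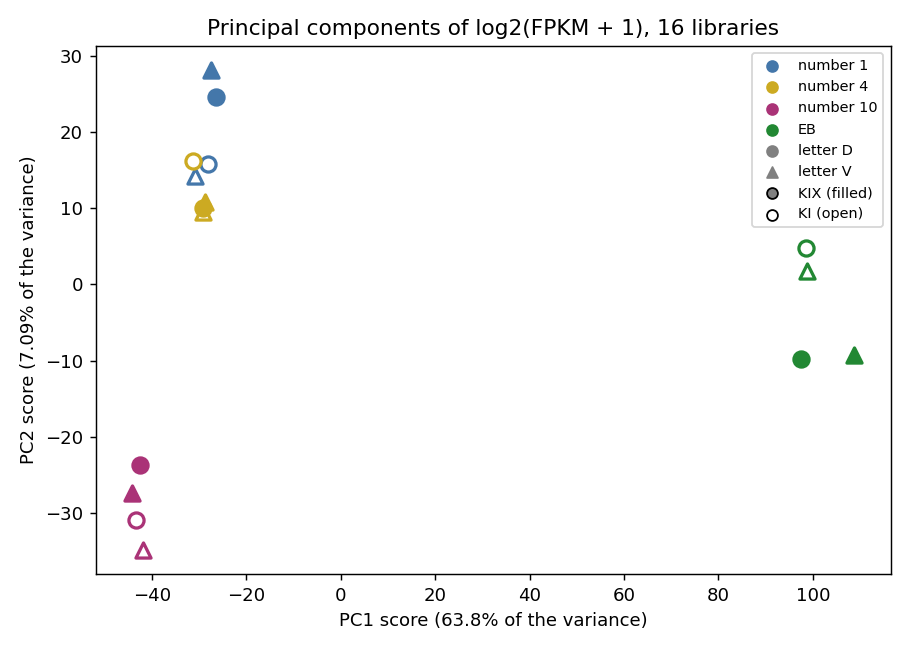
First against second principal component of log2(FPKM + 1) for the 16 libraries, coloured by number or EB, with circles for D, triangles for V, filled marks for KIX and open marks for KI. The 4 EB libraries lie apart on the first component, which holds 63.8% of the variance.

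All 12 genes of the definitive endoderm and liver-type list were higher in EB than in iPSC libraries, and of the 10 lists called this alone also passed with an estimated correlation (adjusted p = 0.00681). Most genes of the extraembryonic endoderm list rose too, so definitive and extraembryonic endoderm were not told apart. Afp, a fetal serum protein, was at 1014 ± 448 FPKM in EBs (n = 4) and 0.139 ± 0.167 in iPSCs (n = 12). Pou5f1, a core pluripotency factor, fell from 989.6 ± 77.7 to 330.1 ± 102 FPKM, a log2 change of -1.64. Nanog, another such factor, fell from 224 ± 39.7 to 40.04 ± 9.25 FPKM. The largest log2 rises were those of S100g (9.99), a calcium-binding protein, Afp (9.70), Ttr (9.20), a thyroid hormone carrier, Spink3 (9.18), a protease inhibitor, Pga5 (8.30), a pepsinogen, and Apob (8.23), a lipoprotein component. The largest falls were those of Ly6a (-6.49), a surface antigen, the chemokines Ccl2 (-6.47), Ccl7 (-6.37) and Ccl8 (-6.13), the matrix protein gene Mgp (-6.33), and Il1rl1 (-5.75), a cytokine receptor. The iPSCs were grown on feeders, so a fall in EBs can reflect lost feeder cells as well as a change within the cells. These were not told apart. Over the libraries of numbers 1 and 4, Mgp (r = 0.852), Il1rl1 (0.948) and Thbd (0.954) followed the fibroblast score. In all, 10960 of 13895 genes tested with limma changed, 5664 of them up. At least 2-fold, 1941 rose and 1617 fell.

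Of the definitive endoderm and liver-type genes, 12 of 12 rose, among them Apoa1 (7.98), which codes for an apolipoprotein (adjusted p = 3.25e-07 in the list test, adjusted p = 0.00681 with an estimated correlation). Of the cardiac muscle genes, 10 of 10 rose, led by Actc1 (5.13), cardiac actin, Tnnt2 (4.30), a troponin, and the myosin heavy chains Myh6 (3.75) and Myh7 (3.69) (adjusted p = 0.00532 in the list test, adjusted p = 0.590 with an estimated correlation). Of 9 extraembryonic endoderm genes, 7 rose, such as the endocytic adaptor Dab2 (5.32) and the visceral endoderm receptor parts Cubn (4.34) and Amn (3.86), and Thbd (-4.06), thrombomodulin, fell (adjusted p = 0.0221, adjusted p = 0.541 with an estimated correlation). Among 9 primitive streak and early mesoderm genes, 6 rose, including Mixl1 (4.08), Eomes (3.05) and Hand1 (2.93), and 2 fell, including T (-3.39), brachyury, from 17.7 ± 12.8 to 0.108 ± 0.0484 FPKM. Of 9 blood and endothelium genes, 5 rose, with Flt1 (4.08), a VEGF receptor, Gata1 (2.17), Cdh5 (1.84) and the embryonic globin Hbb-y (1.76) moving furthest, and 1 fell. Of 7 trophoblast genes, 5 rose, among them Cdx2 (2.17), Gata3 (1.45) and Ascl2 (0.87), and 2 fell, among them Tfap2c (-1.35). Of 20 imprinted genes, 15 rose and 2 fell, led by Dlk1 (3.25), Peg10 (3.04), Meg3 (2.85) and Grb10 (2.74) (adjusted p = 0.00674, adjusted p = 0.541 with an estimated correlation). Of 8 glycolysis genes, 6 rose, including Slc2a1 (1.43), a glucose transporter, Pgk1 (0.94), Pdk1 (0.81) and Aldoa (0.80) (adjusted p = 0.0892).

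Of 12 general pluripotency genes, 10 fell, led by Nanog (-2.46), Dppa2 (-1.91), Tdgf1 (-1.83) and Pou5f1 (-1.64), with Sox2 (-1.32) also lower, and 1 rose (adjusted p = 0.00674, adjusted p = 0.590 with an estimated correlation). Of 12 naive pluripotency genes, 9 fell, including Prdm14 (-2.11), Zfp42 (-1.998), Tcl1 (-1.84) and Dppa3 (-1.61), and 1 rose (adjusted p = 0.00928, adjusted p = 0.541 with an estimated correlation). Of 9 primed or formative epiblast genes, 3 rose, with Fgf5 (3.09) and Otx2 (1.65) the highest, and 2 fell, Zic5 (-1.001) and Pou3f1 (-0.95). All 10 fibroblast (feeder type) genes fell, with the calcium-binding protein S100a4 (-5.67), the collagen Col1a1 (-4.75), the proteoglycan Dcn (-4.71) and the surface glycoprotein Thy1 (-4.60) moving furthest (adjusted p = 0.000996, adjusted p = 0.541 with an estimated correlation). Their mean log2 level, the fibroblast score, was 2.85 ± 1.27 in EBs and 6.01 ± 0.0912 in the libraries of number 4, the lowest of the iPSC numbers. All 8 germ line genes fell, among them Mael (-2.94), Sycp1 (-2.59), Dazl (-2.03) and Stra8 (-1.73) (adjusted p = 0.00138, adjusted p = 0.226 with an estimated correlation). So did 7 of 8 genes of the 2-cell-like state, including Sp110 (-1.95) and Zscan4d (-0.75) (adjusted p = 0.0892), and 4 of 4 neuroectoderm genes, including Tubb3 (-2.37) and Nes (-1.55), too few for a list test. Of 20 Hox genes, 19 fell from low levels, led by Hoxc6 (-1.76), Hoxd13 (-1.73) and Hoxb9 (-1.70), and 1 rose (adjusted p = 0.000208, adjusted p = 0.541 with an estimated correlation). Of 11 cell cycle genes, 9 fell, led by the replication helicase genes Mcm5 (-1.35) and Mcm2 (-1.19), and 1 rose (adjusted p = 0.00928, adjusted p = 0.590 with an estimated correlation).

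Of 9 genes of the DNA methylation machinery, Tet3 (1.93) and 1 other rose, and Uhrf1 (-1.41), Tet1 (-1.27), Tet2 (-0.94) and 1 other fell. The de novo methyltransferase genes Dnmt3a (26.1 ± 4.39 in EBs and 30.8 ± 12.9 in iPSCs, adjusted p = 0.694) and Dnmt3b (172 ± 56.2 and 156 ± 50.6, adjusted p = 0.570) did not pass the test. Of 8 reported miR-203 targets, Bmi1 (0.79) rose and 4 fell, led by Socs3 (-2.03), Snai2 (-1.07) and Zeb2 (-0.88). Of 11 p53 and stress genes, 3 rose, including Atf3 (2.63) and Hspa1a (1.16), and 5 fell, including Bax (-0.78) and Cdkn1a (-0.70). Among the 8 reference genes, B2m (-1.80), Hprt (-1.70) and Ppia (-0.48) fell and Rpl13a (0.39) rose. Of the sex chromosome genes, only Xist (-1.41) was tested, and it fell. Adjusted over the list alone, the counts were the same for each list except blood and endothelium (4 up, 1 down) and p53 and stress (3 up, 4 down).

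Against number 1, number 10 had higher Ccl5 and lower Pgk1 transcripts. The chemokine gene Ccl5 was at 95.4 ± 42.0 FPKM at number 10 and 5.17 ± 1.16 at number 1 (n = 4 each). Pgk1, a glycolytic kinase, was at 447 ± 24.6 and 1346 ± 188. The largest log2 rises were those of Ccl5 (3.87), the interferon-induced Ifit2 (3.55), Cxcl11 (2.96), Cxcl10 (2.83) and Mx1 (2.76), and the pentraxin Ptx3 (2.79). The largest falls were those of T (-3.65), the cornified-layer protein gene Sprr2k (-3.24), Ndufa4l2 (-2.75) and Bnip3 (-2.70), both known to respond to low oxygen, the growth factor gene Fgf8 (-2.71), and Cer1 (-2.53), a Nodal and Wnt antagonist. limma called 3588 of 13080 genes, 1764 up and 1824 down. The count was 1843 without the KIX library of D1 and 1826 without the KIX library of V1. With prefix by number means, chosen after the data were seen, it was 7059.

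Of 8 genes of the 2-cell-like state, 6 rose (7 when adjusted over the list alone), with Zscan4f (1.04), Zscan4d (1.04), Zscan4c (1.03) and Zscan4a (0.90) at 1.20 to 1.59 FPKM at number 10 (adjusted p = 0.000949 in the list test, adjusted p = 0.108 with an estimated correlation). Of 8 glycolysis genes, 5 fell by either adjustment, including Pgk1 (-1.58), the glucose transporter gene Slc2a1 (-1.38), lactate dehydrogenase Ldha (-1.004) and Pfkp (-0.95) (adjusted p = 0.00153, adjusted p = 0.541 with an estimated correlation). Of 5 trophoblast genes, 4 fell, Krt7 (-1.11), Tfap2c (-0.90), Ascl2 (-0.79) and Cdx2 (-0.79) (adjusted p = 0.0134, adjusted p = 0.535 with an estimated correlation). No other list was called. Among 8 streak and early mesoderm genes, 4 fell, including Mixl1 (-1.86), Eomes (-1.22) and Msgn1 (-1.10), and 1 rose. Of 9 primed or formative epiblast genes, 4 fell, Fgf5 (-1.42), Otx2 (-1.35), Fgf15 (-0.80) and Zic2 (-0.70). Of 4 neuroectoderm genes 2 fell (Nes (-0.69) and Elavl3 (-0.61)). Of 4 cardiac muscle genes 2 fell (Myl7 (-1.17) and Actc1 (-1.06)). Of 6 endoderm genes 2 fell (Foxa2 (-2.22) and Cxcr4 (-0.58); 3 when adjusted over the list alone). Zfp42 (0.64) of the naive list, Dppa2 (0.36) of the general list, Sox7 (0.67) and Dab2 (0.56) of extraembryonic endoderm and Socs3 (0.94) and Snai2 (1.02) of the reported targets rose. Of 10 fibroblast genes, Lum (-0.93) and Fap (-0.30) fell and Col3a1 (0.60) rose, beside a fibroblast score of 6.53 ± 0.310 at number 10 and 6.73 ± 0.260 at number 1. Of 20 imprinted genes, 4 rose, including Plagl1 (0.57) and Mest (0.55), and 2 fell. Of 10 p53 and stress genes, 2 rose and 4 fell (6 when adjusted over the list alone), led by Atf3 (-1.34). In blood and endothelium Lmo2 (0.86) rose and Flt1 (-0.72) fell. In the germ line list Tex101 (0.42) rose and Sycp3 (-0.94) fell, and in the reference list B2m (0.78) rose and Hprt (-0.87) fell. Among 19 Hox genes 2 rose, including Hoxa13 (0.76), and Hoxb1 (-0.94) fell, and in the cell cycle list Bub1 (-0.46) fell. Xist and the 9 genes of the DNA methylation machinery did not pass. Dnmt3a was at 40.7 ± 12.6 and 32.6 ± 8.24 FPKM (adjusted p = 0.573) and Dnmt3b at 194 ± 39.1 and 167 ± 26.5 (adjusted p = 0.603). The prefixes went opposite ways for Dnmt3a. In D and V of KIX it was at 48.7 and 52.4 FPKM at number 10 and 26.1 and 24.95 at number 1. In KI it was at 24.5 and 37.2 and at 40.8 and 38.6. Pou5f1 (1002 ± 126 and 963 ± 27.0), Nanog (199 ± 32.3 and 204 ± 23.2) and Sox2 (149 ± 18.1 and 135 ± 8.86) did not pass either.

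**Figure D3:**
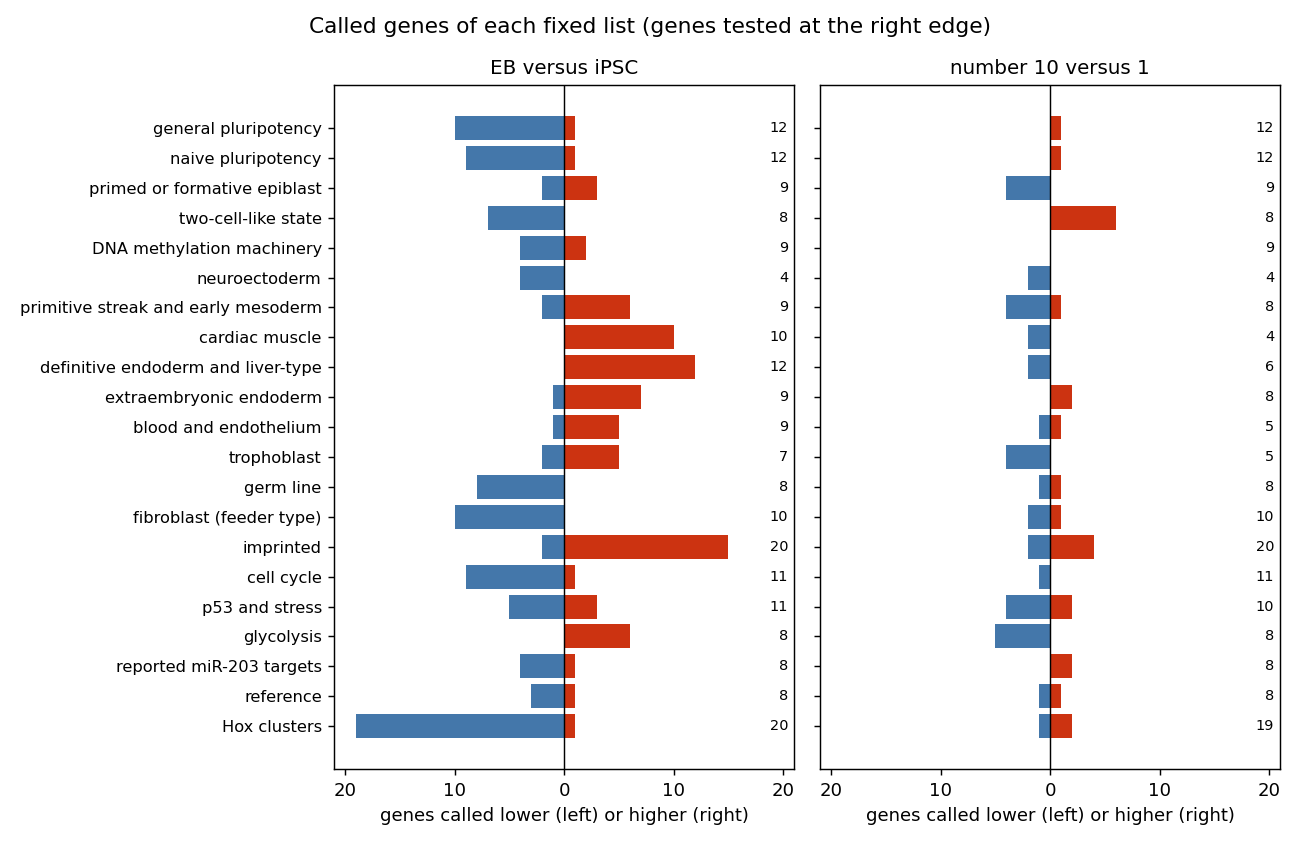
Number of genes of each list called lower (left) or higher (right) in EB against iPSC libraries and in number 10 against number 1, with the number tested at the right edge. All 12 endoderm and liver-type genes rose in EBs, and 6 of 8 genes of the 2-cell-like state rose at number 10.

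Against number 1, number 4 had lower Cxcl10 and higher H2-K1 transcripts, and 4 of 10 fibroblast genes were lower. Cxcl10, an interferon-induced chemokine gene, fell from 73.6 ± 17.1 to 4.49 ± 1.14 FPKM. H2-K1, an MHC class I heavy chain gene, rose from 68.3 ± 2.36 to 269 ± 32.8 FPKM (n = 4 each). The largest rises were those of Ccl5 (3.77), H2-Q6 (2.39), H2-Q7 (2.22), H2-Q4 (2.01), H2-K1 (1.96) and S100a8 (1.68), and the largest falls were those of Cxcl10 (-3.75), Sprr2k (-3.27), Rsad2 (-3.04), Crct1 (-2.68), Cmpk2 (-2.63) and Ifit3 (-2.50). Of 10 fibroblast genes, 4 fell (8 when adjusted over the list alone), Lum (-1.56), Postn (-1.40), Col1a2 (-0.89) and Dcn (-0.78), the last at 2.56e-05 with the fibroblast score, of which it is part, as a covariate, beside fibroblast scores of 6.01 ± 0.0912 at number 4 and 6.73 ± 0.260 at number 1 (adjusted p = 0.000151, adjusted p = 0.682 with an estimated correlation). The primed list (2 of 9 down, Fgf15 (-1.47) and Zic2 (-0.86), 4 over the list alone; adjusted p = 0.0165, adjusted p = 0.682 with an estimated correlation) and glycolysis (0 of 8 called, 6 down over the list alone; adjusted p = 0.00935, adjusted p = 0.682 with an estimated correlation) lay lower only at the preset correlation. The endoderm list (1 of 6 up, Sox17 (0.78), 4 over the list alone; adjusted p = 0.00600, adjusted p = 0.184 with an estimated correlation) and the 2-cell-like state (1 of 8 up; adjusted p = 0.0104, adjusted p = 0.184 with an estimated correlation) lay higher only at the preset correlation. Nanog (0.39), Zfp42 (0.43) and Tfcp2l1 (0.91) rose, while Dnmt3a (19.1 ± 8.22 and 32.6 ± 8.24 FPKM, adjusted p = 0.175) and Dnmt3b (107 ± 42.9 and 167 ± 26.5, adjusted p = 0.133) did not pass. Their spread holds the difference between KI and KIX, and within each prefix both genes were lower at number 4 without overlap. Dnmt3a in D and V went from 40.8 and 38.6 to 25.4 and 27.0 FPKM in KI. In KIX it went from 26.1 and 24.95 to 11.4 and 12.7. Dnmt3b went from 195 and 183 to 123 and 160 in KI and from 145 and 144 to 68.8 and 75.6 in KIX. limma called 1138 genes, 418 up and 720 down, a share of 36.7% up that became 49.8% after quantile normalization. With the fibroblast score as a covariate 769 were called and the majority turned, with 567 up and 202 down. Number means alone gave 2306 genes and prefix by number means, chosen after the data were seen, 5360. Without 1 library the count was 318 (KI of D1), 384 (KI of V1), 336 (KIX of D1), 329 (KIX of V1), 672 (KI of V4) or 346 (KIX of V4).

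Against number 4, number 10 had lower transcripts of 5 of 6 endoderm genes and higher Cxcl10. Cxcl10 rose from 4.49 ± 1.14 to 541 ± 194 FPKM (n = 4 each), and with it Ifit2 (5.47), Rsad2 (4.54), Cmpk2 (4.49), Mx1 (4.19) and Ifit3 (4.16) had the largest rises. The largest falls were those of Cer1 (-3.49), T (-3.31), Fgf8 (-3.12), the retinoic acid hydroxylase gene Cyp26a1 (-3.01), the keratin gene Krt8 (-2.63) and Gsc (-2.58), a streak homeobox gene. Of 6 endoderm genes, 5 fell (6 over the list alone), including Foxa2 (-2.47), Sox17 (-1.28) and Gata6 (-0.84) (adjusted p = 2.99e-05, adjusted p = 0.0605 with an estimated correlation). The streak list (2 of 8 down, among them Mixl1 (-1.90), 3 over the list alone; adjusted p = 0.0495, adjusted p = 0.630 with an estimated correlation) lay lower only at the preset correlation. The fibroblast list (2 of 10 up, Col3a1 (1.19) and Postn (1.10), 5 over the list alone; adjusted p = 0.0227, adjusted p = 0.692 with an estimated correlation) and the 2-cell-like state (3 of 8 up, led by Zscan4f (0.73), 4 over the list alone; adjusted p = 0.0309, adjusted p = 0.256 with an estimated correlation) lay higher, likewise only there. Dnmt3a (40.7 ± 12.6 and 19.1 ± 8.22 FPKM, adjusted p = 0.0771) and Dnmt3b (194 ± 39.1 and 107 ± 42.9, adjusted p = 0.0619) did not pass, and Nanog (-0.44) fell. Dnmt3a in D and V of KIX was at 48.7 and 52.4 FPKM at number 10 and 11.4 and 12.7 at number 4. In KI, where it overlapped, it was at 24.5 and 37.2 and at 25.4 and 27.0. limma called 1544 genes, 936 up and 608 down, a share of 60.6% up that became 44.9% after quantile normalization. The count was 964 without the KI library of D4, 614 without the KIX library of V4, 1026 without the KI library of D10, 995 without the KIX library of D10 and 728 with the fibroblast score as a covariate. It was 2802 with number means alone, 860 with library weights and 5583 with prefix by number means.

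Between the letters D and V limma called hardly any gene. In iPSCs (n = 6 each) the 4 genes called were small-RNA genes, chosen for mention after their values were seen: Mir26b (1.85), Mir3061 (1.63) and Snord95 (2.78) were higher in D and Mir705 (-1.87) was lower. All 4 calls were kept with the prefix as a block. They were lost with an additive model of number and letter (0 genes in limma, 94 at an unadjusted p under 0.05) and with prefix by number means (0 and 490), which make each pair of libraries of 1 prefix and number a block. The planned fit had 74 of 13080 genes at such a p, a share far below the 0.05 that chance alone gives. Its spread holds the difference between KI and KIX, so its p-values are too large here. Few calls in it therefore do not show that D and V are alike, though prefix by number means, which remove that difference, called 0 as well. Pou5f1 was at 991 ± 84.6 FPKM in D and 988 ± 78.1 in V, Nanog at 229.5 ± 35.2 and 218 ± 46.2, Dnmt3a at 29.5 ± 13.3 and 32.1 ± 13.7, and Dnmt3b at 147 ± 49.4 and 165 ± 54.6, each with an adjusted p of at least 0.9998. The same kind of gene made up the calls at number 1 (Mir26b (5.56) and Mir3061 (4.90)), at number 10 (Snord95 (8.29) and Mir705 (-5.60)) and in EBs (Mir302a (-7.88) and Mir409 (-6.33)). At number 4 limma called 0 genes, with 116 at an unadjusted p under 0.05, and leaving out any 1 of the 8 libraries of numbers 1 and 4 gave 1 gene. The D minus V difference itself differed between EBs and iPSCs for 4 genes (Mir26b (-1.85), Mir302a (-7.88), Mir409 (-6.33) and Mir705 (1.87)) and between numbers 10 and 1 for 4 (Mir26b (-5.56), Mir3061 (-4.90), Mir705 (-5.60) and Snord95 (8.24)). These genes are short and mostly at 0, so 1 fragment can move them far. Without the KI library of V in EBs the EB count became 40 and the count for EB minus iPSC became 29. It became 5 and 7 without the KI library of D in EBs, 4 and 7 without the KIX library of D, and 4 for EBs without the KIX library of V. Without the KIX library of D1 the iPSC count was 2 and the count at number 1 was 1. Without the KI library of D1 the count at number 1 was 0 (39 at an unadjusted p under 0.05) and that for 10 minus 1 was 2, and without the KIX library of V10 the count at number 10 was 1.

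Of the genes of the fixed lists named by the rule, 45 in iPSCs, none passed between D and V, with changes from -0.51 (T) to 0.18 (Zscan4d) and no adjusted p under 0.9998. The range was -0.29 to 0.50 at number 1, -0.39 to 0.33 at number 4, -1.28 to 0.53 at number 10 and -1.23 to 1.48 in EBs. For the differences it was -1.11 to 1.54 (EB minus iPSC) and -1.41 to 0.59 (10 minus 1). As a list, the 2-cell-like state was higher in D in iPSCs by a median of 0.26 (0 of 8 genes called, 1 over the list alone; adjusted p = 8.91e-10, adjusted p = 0.00932 with an estimated correlation) and at number 10 by 0.52 (1 of 8 over the list alone; adjusted p = 2.45e-09, adjusted p = 0.0106 with an estimated correlation). Its difference also differed between numbers 10 and 1 (median 0.51, adjusted p = 1.98e-05, adjusted p = 0.0442 with an estimated correlation). Levels were low: in iPSCs Zscan4d of this list was at 0.977 ± 0.895 FPKM in D and 0.665 ± 0.536 in V. Its change was -0.066 at number 1, 0.087 at number 4 and 0.53 at number 10. The list holds several Zscan4 genes, which may share reads, so its tests can count 1 signal several times. Sp110, also of this list, was at 4.60 ± 3.85 and 4.79 ± 3.94 in iPSCs (-0.039). Of 19 lists in iPSCs, 3 were called (2 with the prefix as a block), the others being naive pluripotency (median 0.10, adjusted p = 0.00669, adjusted p = 0.357 with an estimated correlation) and glycolysis (median 0.09, adjusted p = 0.0411, adjusted p = 0.920 with an estimated correlation).

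KIX against KI over all 16 libraries (n = 8 each) gave 9 genes, all lower in KIX. Fgf5, a marker of the primed epiblast, was at 9.10 ± 11.4 FPKM in KIX and 21.9 ± 27.7 in KI, a change of -1.01. The others, of which the rule names none because their libraries overlap between the sides, were Car4 (-0.99), Foxj1 (-0.89), Psors1c2 (-0.74), Fgfbp1 (-0.67), Mogat2 (-0.50), Slc39a4 (-0.44), Fgd1 (-0.42) and Steap3 (-0.40). The primed or formative epiblast list lay lower in KIX only at the preset correlation (1 of 9 called, 4 over the list alone; adjusted p = 8.99e-06, adjusted p = 0.473 with an estimated correlation). Dnmt3a (-0.15, adjusted p = 0.843), Dnmt3b (-0.44, adjusted p = 0.382) and Pou5f1 (-0.13, adjusted p = 0.759) did not pass. The count was 3 without the KI or the KIX library of D1 or V1, 2 without either library of V4, 2 without the KI and 3 without the KIX library of D in EBs, and 15 after quantile normalization, of which 13.3% were higher in KIX. It was 2329 when each number and EB had its own KIX and KI means, so the prefixes were then compared within each of them, a step chosen after the data were seen.

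The comparisons of KIX with KI within each number and within EBs, with the letters D and V as 2 replicates, were added after the data were seen. At number 1 (n = 2 each) the proto-oncogene Myc was at 76.7 ± 1.04 FPKM in KIX and 24.4 ± 2.13 in KI. The naive pluripotency factor Klf4 was at 59.6 ± 2.78 and 28.7 ± 1.27. The rule leaves out microRNA genes such as Mir203, which was at 1868 and 1969 FPKM in KIX and 0 in KI. Among the other genes the largest rises were those of Atp2a3 (2.25), a calcium pump, Krtdap (2.19), Nefl (1.91), a neurofilament, Adap1 (1.64), Myc (1.62) and Krt13 (1.49). The largest falls were those of Msgn1 (-1.31), Car3 (-1.06), Foxj1 (-1.04), Gadd45g (-0.85), Rapgef1 (-0.80) and the imprinted Meg3 (-0.79). Klf4 (1.03) and Tcl1 (0.69) of 12 naive genes rose, and 2 of 20 imprinted genes fell (8 over the list alone; adjusted p = 2.82e-06, adjusted p = 0.381 with an estimated correlation). Dnmt3a was at 25.5 ± 0.798 and 39.7 ± 1.57 FPKM (adjusted p = 0.0867) and Dnmt3b at 144 ± 0.794 and 189 ± 8.47 (adjusted p = 0.215), neither of which passed. Of 19 lists, 7 were called and none with an estimated correlation. Of 8 reported miR-203 targets, Socs3 (-0.41) fell (2 over the list alone; adjusted p = 0.00119, adjusted p = 0.381 with an estimated correlation). limma called 273 genes, 200 up, and 128 with the fibroblast score (6.61 ± 0.0232 in KIX and 6.84 ± 0.385 in KI) as a covariate. Without 1 library the count was 65 (KI of D1), 87 (KI of V1), 60 (KIX of D1), 25 (KIX of V1), 436 (KI of D4), 432 (KI of V4) or 167 (KIX of D10 or of V10).

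At number 4, Dnmt3a, Dnmt3b and Dnmt3l were lower in KIX (n = 2 each). Dnmt3a was at 12.1 ± 0.902 FPKM in KIX and 26.2 ± 1.17 in KI (-1.06), and Dnmt3b at 72.2 ± 4.83 and 142 ± 26.2 (-0.95). Their cofactor Dnmt3l was at 45.3 ± 0.643 and 108 ± 3.54 (-1.23), while Tet2 (1.18) rose. Of 12 naive genes, 5 rose (7 over the list alone), among them Tcl1 (1.14), Tbx3 (1.09) and Klf4 (1.00), and 2 fell, led by Dppa3 (-1.25). Of 9 primed genes, 6 fell (9 over the list alone), among them Lef1 (-2.22), a Wnt effector, Pou3f1 (-1.19), Sox3 (-1.03) and Otx2 (-0.95) (adjusted p = 7.24e-06, adjusted p = 0.646 with an estimated correlation). Of 8 glycolysis genes, 6 fell, including Pgk1 (-0.92) and Ldha (-0.74) (adjusted p = 0.00126, adjusted p = 0.646 with an estimated correlation). Of 12 general pluripotency genes 4 fell, led by Tdgf1 (-0.52) and Utf1 (-0.45) (adjusted p = 0.0101, adjusted p = 0.646 with an estimated correlation). Of 19 lists, 4 were called and none with an estimated correlation. Leaving out microRNA genes such as Mir203 (2254 and 1728 FPKM in KIX and 0 in KI), the largest rises were those of Pramel7 (2.77), Atp2a3 (2.62), Rpl34 (2.60), Obox6 (2.50), Sp110 (2.47) and Pramel6 (2.38). The largest falls were those of Rps27 (-3.08), Ndufa4l2 (-2.39), Lef1 (-2.22), Mt3 (-2.08), Bnip3 (-2.05) and Egln3 (-1.86). Rpl34 and Rps27 have near-identical pseudogenes and are uncertain. The fibroblast score was 6.01 ± 0.0351 in KIX and 6.01 ± 0.154 in KI. limma called 2612 genes, 1490 up, a share of 57.0% that became 47.5% after quantile normalization (1223 up and 1352 down). The count was 1466 without the KI library of D4, 870 without the KIX library of D4 and 1080 without the KIX library of V4.

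At number 10, Dnmt3a and Dnmt3l were higher in KIX (n = 2 each). Dnmt3a was at 50.6 ± 2.62 FPKM in KIX and 30.9 ± 8.95 in KI (0.72). Dnmt3l was at 196 ± 8.79 and 121 ± 20.3 (0.71), and Dnmt3b at 222 ± 25.6 and 167 ± 30.3 (adjusted p = 0.0672). Of 9 DNA methylation genes, 5 rose (7 over the list alone; adjusted p = 0.00194, adjusted p = 0.258 with an estimated correlation). Of 12 general pluripotency genes 8 rose, including Dppa4 (0.49), Utf1 (0.42) and Pou5f1 (0.31) (10 over the list alone; adjusted p = 0.000429, adjusted p = 0.258 with an estimated correlation). Of 11 cell cycle genes 5 rose, including Mcm2 (0.36) and Top2a (0.35) (10 over the list alone; adjusted p = 0.000146, adjusted p = 0.258 with an estimated correlation). Of 10 fibroblast genes, 6 fell, including S100a4 (-0.73), Col1a2 (-0.65) and Col3a1 (-0.64) (8 over the list alone; adjusted p = 0.00342, adjusted p = 0.541 with an estimated correlation). Of 19 Hox genes 5 fell (6 over the list alone; adjusted p = 0.000480, adjusted p = 0.258 with an estimated correlation), and of 8 reported targets 4 fell, among them Snai2 (-0.65) and Zeb2 (-0.65), and Dnmt3a rose (adjusted p = 0.545 for the list). Of 19 lists, 7 were called and none with an estimated correlation. The largest rises were those of Rpl39l (1.41), Gbx2 (1.29), Cyp2b23 (1.23), Mep1b (1.23), Magea8 (1.14) and Xlr3c (1.14). The largest falls were those of Rhox9 (-1.77), Rhox6 (-1.57), Ptx3 (-1.46), Fgf8 (-1.41), Mt2 (-1.29) and Krt8 (-1.28). The fibroblast score was 6.26 ± 0.00959 in KIX and 6.79 ± 0.1295 in KI, so it moved with these groups. limma called 3384 genes, 1386 up, and 31 with that score as a covariate. The median size of the change of the 3384 genes then went from 0.40 to 0.30 and its median SE from 0.0896 to 0.127. The count was 1188 without the KI library of V10, 503 without the KIX library of D10 and 1611 without the KIX library of V10.

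**Figure D4:**
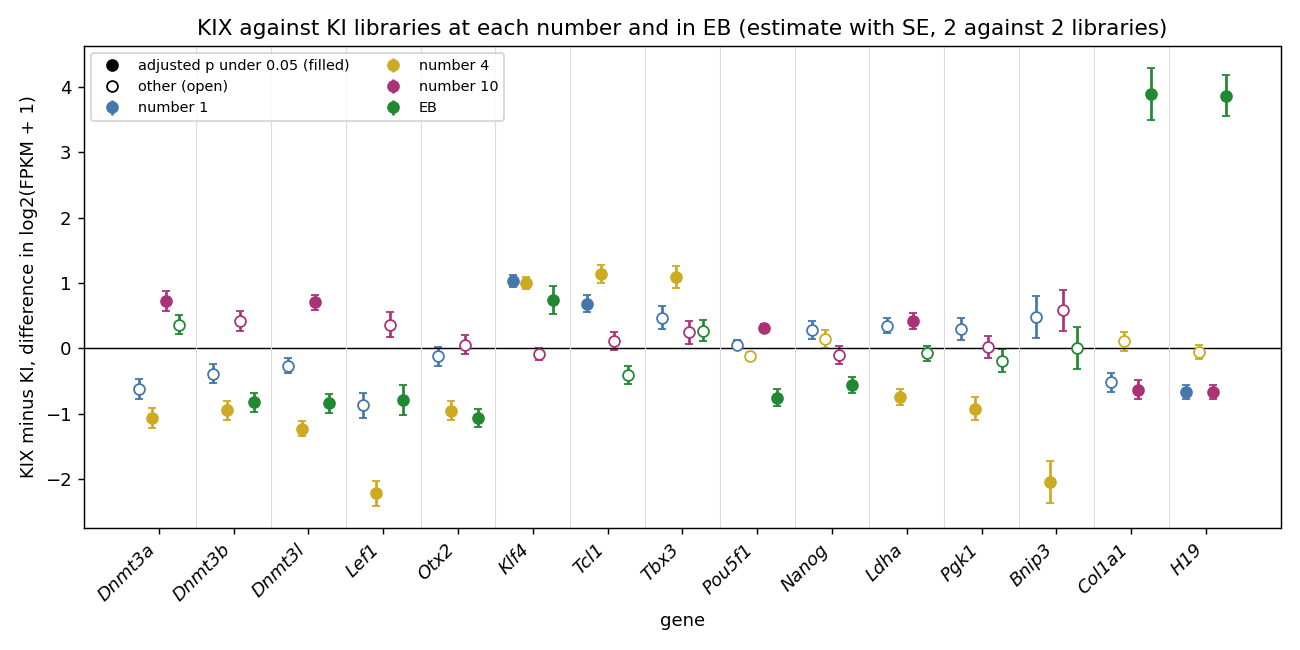
Difference of log2(FPKM + 1) between KIX and KI libraries, with its SE, for 15 genes at numbers 1, 4 and 10 and in EBs (n = 2 each), filled where the adjusted p was under 0.05. Dnmt3a was lower in KIX by a log2 difference of -1.06 at number 4 and higher by 0.72 at number 10.

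The change of the KIX minus KI difference between numbers was tested directly. From number 4 to 10 it moved up by 1.94 for Dnmt3l, 1.79 for Dnmt3a, 1.37 for Dnmt3b, 2.58 for Lef1 and 1.16 for Ldha. It moved down for Klf4 (-1.09) and Tcl1 (-1.02). Of 8 glycolysis genes 7 moved up (adjusted p = 3.90e-05, adjusted p = 0.410 with an estimated correlation). Of 9 primed genes 6 did, 7 over the list alone (adjusted p = 3.90e-05, adjusted p = 0.410 with an estimated correlation). Nanog (-0.24, adjusted p = 0.360) did not pass. limma called 3986 genes, 1617 up, a share of 40.6% that became 51.9% after quantile normalization. The count was 1861 without the KIX library of D4, 1913 without the KIX library of D10, 2556 without the KIX library of V10 and 1023 with the fibroblast score as a covariate.

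From number 1 to 4 the difference moved down for Ndufa4l2 (-3.23), Bnip3 (-2.53), Lef1 (-1.34), Pgk1 (-1.22) and Dnmt3l (-0.96) and up for Bhmt (2.31), a betaine-homocysteine methyltransferase. Dnmt3a (-0.44, adjusted p = 0.227) and Dnmt3b (-0.56, adjusted p = 0.139) did not pass. limma called 527 genes, 274 up, and 320 with the fibroblast score as a covariate. Without 1 library the count was 117 (KI of D1), 239 (KI of V1), 48 (KIX of D1), 73 (KIX of V1), 235 (KI of D4), 2658 (KI of V4), 44 (KIX of D4), 128 (KIX of V4) or 262 (KIX of D10 or of V10).

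In EBs, Pou5f1, Otx2 and Dnmt3b were lower in KIX and Afp was higher (n = 2 each). Pou5f1 was at 248 ± 63.4 FPKM in KIX and 412 ± 0.805 in KI, and Otx2 at 50.9 ± 4.74 and 108 ± 4.93. Dnmt3b was at 124 ± 14.5 and 219.5 ± 7.88, and Afp at 1391 ± 181 and 636 ± 23.3. Of 12 general pluripotency genes 11 fell, including Fgf4 (-0.89) and Nanog (-0.56) (adjusted p = 7.41e-06, adjusted p = 0.301 with an estimated correlation). Of 9 primed genes 8 fell (adjusted p = 0.000521, adjusted p = 0.301 with an estimated correlation). Of 10 cardiac muscle genes 9 rose, among them Myh7 (1.94), Myl4 (1.77) and Nkx2-5 (1.73) (adjusted p = 3.84e-05, adjusted p = 0.301 with an estimated correlation). Their spread in KIX was wide, with Myh7 at 39.6 ± 36.9 FPKM, and it was at 65.7 FPKM in the KIX library of V and 13.5 in that of D, against 6.75 and 7.55 in the KI libraries. The number of cardiac genes called up fell to 3 of 10 without the KI library of D, to 3 of 10 without that of V and to 5 of 9 without the KIX library of V. Of 20 imprinted genes 11 rose, including H19 (3.86), Plagl1 (2.62) and Dlk1 (2.56), and 2 fell (adjusted p = 3.84e-05, adjusted p = 0.301 with an estimated correlation). Of 10 fibroblast genes 7 rose (8 over the list alone), with Col1a1 at 58.7 ± 39.8 and 2.75 ± 1.67 FPKM (adjusted p = 1.07e-05, adjusted p = 0.301 with an estimated correlation), and the fibroblast score was 3.84 ± 0.855 in KIX and 1.85 ± 0.416 in KI. Of 20 lists, 12 were called and none with an estimated correlation. The largest rises were those of Col1a1 (3.89), H19 (3.86), Col3a1 (3.18), Postn (3.03), Alb (2.93) and Hba-x (2.91). Alb (13.8 ± 14.9 FPKM in KIX) and Hba-x (13.0 ± 16.2) differed widely between the KIX libraries. The change of Alb was 1.65 without the KIX library of V, that of Hba-x was 1.23 without the KIX library of D, and Hba-x was no longer called without either KI library. Among the largest falls were Prl2a1 (-2.48), the Nodal antagonist Lefty1 (-1.98), Sox3 (-1.84), the Nodal co-receptor Cfc1 (-1.64) and Coch (-1.62), with the small nuclear RNA gene Rnu11 listed at 0 in both KIX libraries. Among the reported miR-203 targets, Zeb2 (1.17), Snai2 (0.70) and Abl1 (0.28) were higher and Dnmt3b (-0.83) was lower. Snai2 and Zeb2 thus ran opposite ways at number 10 and in EBs, as the fibroblast score did. Dnmt3a did not pass (0.36, adjusted p = 0.0924). limma called 3796 genes, 1718 up, and 2489 without the KI library of D, 1946 without the KI library of V and 2429 without the KIX library of V.

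These comparisons of KIX with KI within a number use different libraries, so their overlaps carry no shared controls. Those at numbers 1, 4 and 10 share 1 estimate of each gene's spread, and the EB fit also uses the iPSC libraries. Genes with a small spread are thus called more readily in all of them, which can raise overlaps in either direction. Fisher's exact test also takes genes as independent, so its p-values overstate the evidence. Of the genes higher in KIX at number 1, 132 were also higher at number 4, where independent lists would share 22.8 (Fisher's exact test, adjusted p = 1.83e-75 over 24 overlaps), and 8 were lower against 17.2 (adjusted p = 0.0217). Of those lower at number 1, 44 were lower at number 4 against 6.26 (adjusted p = 3.53e-28) and 0 were higher against 8.32 (adjusted p = 0.000473). Between numbers 1 and 10, 44 genes were higher at both against 21.2 (adjusted p = 4.37e-06) and 20 lower at both against 11.15 (adjusted p = 0.0120), while 22 were higher at 1 and lower at 10 against 30.6 (adjusted p = 0.117) and 12 the reverse against 7.735 (adjusted p = 0.148). Between numbers 4 and 10, 235 genes were higher at both against 158 (adjusted p = 1.30e-10), 76 were lower at both against 171 (adjusted p = 5.38e-19), and 214 were lower at 4 and higher at 10 against 119 (adjusted p = 1.59e-18). Another 211 were higher at 4 and lower at 10 against 228 (adjusted p = 0.231).

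With EBs, 53 genes higher at number 1 were lower in EBs against 30.2 (adjusted p = 4.52e-05) and 27 higher against 21.2 (adjusted p = 0.219). Of those lower at number 1, 16 were higher in EBs against 7.72 (adjusted p = 0.00603) and 15 lower against 11.03 (adjusted p = 0.218). Of the genes lower at number 4, 346 were lower in EBs too against 170 (adjusted p = 8.34e-44) and 65 higher against 119 (adjusted p = 1.32e-08). Of those higher at number 4, 184 were higher in EBs against 158 (adjusted p = 0.0266) and 210 lower against 225 (adjusted p = 0.249), so the overlap lay mainly in the lower genes. Of those higher at number 10, 530 were lower in EBs against 210 (adjusted p = 3.11e-112) and 53 higher against 147 (adjusted p = 1.91e-21). Of those lower at number 10, 538 were higher in EBs against 211 (adjusted p = 2.78e-115) and 137 lower against 302 (adjusted p = 4.90e-33). The fibroblast score also ran opposite ways, at 6.26 in KIX and 6.79 in KI at number 10 and at 3.84 and 1.85 in EBs.

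Genes whose longest annotated 3′ UTR holds CATTTCA, the match to bases 2 to 8 of miR-203-3p, were compared with genes without it. Dnmt3a and Dnmt3b each hold 1 such site in the 3′ UTR, at 3913198 to 3913204 of chromosome 12 (exon 23 of 23) and at 153687445 to 153687451 of chromosome 2 (exon 24 of 24, GRCm38), and Dnmt3l holds none. The p-values are those of limma's camera, adjusted over 13 comparisons, and none of them was under 0.5476 with an estimated correlation. Between KIX and KI at number 1, the 2141 genes with a site lay lower than the other genes by a median of -0.0141 (adjusted p = 0.570), a value that 4 of 100 shuffled heptamers of the same bases matched or went below. Genes with the longer match CATTTCAA lay lower by -0.0222 (adjusted p = 0.423), below all 100 shuffled octamers, a set added after the data were seen. At number 4 the difference was 0.0586 in the other direction (adjusted p = 0.0697), with 61 of 100 heptamers as low, and it was -0.0199 at number 10 (29 of 100) and 0.0304 in EBs (49 of 100). Between D and V the difference was -0.0186 in iPSCs (adjusted p = 0.00738), with 24 of 100 heptamers as low, and -0.0217 for the longer match, with 16 of 100 octamers as low. It was 0.0248 at number 1 (adjusted p = 0.0231, 88 of 100), -0.0537 at number 4 (adjusted p = 1.00e-05, 15 of 100), -0.0250 at number 10 (adjusted p = 0.0732, 41 of 100) and -0.0405 in EBs (adjusted p = 0.00738, 19 of 100). Against genes of the same UTR length decile, only the call at number 4 among these passed (a mean difference of -0.0145, adjusted p = 0.0130 by permutation). Between numbers, the difference was -0.0300 for 10 against 1 (86 of 100), -0.0614 for 4 against 1 (adjusted p = 0.0231, 50 of 100) and 0.0299 for 10 against 4 (94 of 100). It was 0.204 between EBs and iPSCs (adjusted p = 0.0556, 73 of 100).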

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

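The tests for exchanged labels and for the direction of the calls, the comparisons of KIX with KI within numbers and in EBs, their changes between numbers and the second feeder test in EBs were chosen only after results had been seen. In 39 sets of 4 libraries, 2 held a library far from its fellows, where chance gives about 1 set in 20. Among the libraries of number 1 the KI library of D1 had a fibroblast score of 7.115 against 6.57 to 6.63 in the others, a gap of 0.895 of the range. Among the EB libraries the KIX library of V had 6.77% of its FPKM in its 10 most abundant genes against 7.09% to 7.14% in the others, a gap of 0.862 of the range. The D minus V difference changed between EBs and iPSCs for 4 genes and between numbers 10 and 1 for 4 genes, all of them short RNA genes. The KIX minus KI difference changed from number 1 to number 4 for 527 genes.

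From number 4 to number 10 the KIX minus KI difference changed for 3986 genes, with moves of 1.79 for Dnmt3a, 1.37 for Dnmt3b and 0.43 for Pou5f1. With the fibroblast score as a covariate 95.84% of these genes had the same sign and at least 50% of the size. The calls fell to 1023 as the median change went from 0.55 to 0.45 and its median SE from 0.124 to 0.149. With prefix by number means this covariate is fitted only on differences between D and V within a prefix and number. The score's SD there was 0.385 for KI at number 1 but 0.0351 or less in KIX, so this test alone decides nothing. Feeder content as the whole cause is argued against by number 4, where the mean score was 6.01 in both prefixes and 2612 genes differed. Median-ratio rescaling decides nothing: it moved the median of all genes only from -0.04 to -0.01, so that 100% had to do so. A single factor per library moves all genes one way and is argued against as the whole cause, since 40.57% of the calls moved up and the rest down. Exchanged KI and KIX labels at number 10 stay open, since 59.7% of the genes called at number 1 had the same sign at number 10, between the bounds of 40% and 60% set for it, 44 genes were higher in KIX at both numbers against 21.2 for independent lists and 20 lower at both against 11.15, 22 turned from higher to lower against 30.6 and 12 from lower to higher against 7.735, and Mir203 was listed at 0 in all 4 libraries of that number. A lasting effect of the miR-203 pulse is a biological hypothesis that may apply, but the labels do not say which libraries were induced or when, so it was not tested.

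At number 10, KIX libraries had a lower fibroblast score than KI libraries, and fewer feeder cells may account for part of the 3384 calls. The 1992 lower genes outside the fibroblast list had a median correlation with the score of 0.1152 over the 8 libraries of numbers 1 and 4, against a median of 0.0871 over 10000 random lists and an upper bound of 0.134 set from them. Of 24 pluripotency genes 14, or 58.33%, rose by at least 50% of the median rise of called genes, under a bound of 60% but with an exact binomial interval of 36.6% to 77.9%. Both values met the bound set against feeders only by less than their spread, so feeders and a change within the iPSCs cannot be told apart here. With the score as a covariate 31 genes were called, while 83.69% of the 3384 kept their sign and at least 50% of their size. The size of the change went from 0.40 to 0.30 and its SE from 0.0896 to 0.127. This covariate is fitted only on the differences between D and V named above, so it does not decide either.

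In EBs, 7 of 10 fibroblast genes were higher in KIX. Feeder cells carried into these libraries should add each gene in proportion to its level in the iPSC cultures, but the gain over KI was 58.8% of that level for Lum, 35.7% for Postn and 30.5% for Col3a1 against 0.852% for Thy1, 1.46% for S100a4 and 3.26% for Dcn. Of the 10 genes, 50% lay within 3-fold of the median gain of 14.8%, a value between the bounds set for this test, so it alone decided nothing. A second test on 45 other genes that follow the fibroblast score gave a median gain of 3.86% with a bootstrap interval of 1.98% to 6.73%, which spans the bound of 4.94% below which it would argue against feeders. These genes ranged from Mgp at 0.465% and Mmp3 at 0.575% to Col5a1 at 19.9% and Cdh11 at 27.6% and 15 of them lay above 50% of the median of the list. Without the 7 that belong to a list of 15 interferon-induced genes, made after the data were seen, the median was 3.51%, so these do not hold it down. Carried feeders therefore stay open, beside mesenchymal cells formed in the EBs as a possible explanation that was not tested.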

How the results depend on the processing

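Prefix by number means, the fibroblast score as a covariate and the comparisons of KIX with KI within numbers, within EBs and between numbers, with their alternatives, and the adjustment of the seed-match p-values over 13 comparisons were chosen only after the data were seen, and the cause of the changes given here was not tested. Prefix by number means, in which D and V are replicates, raised the calls to 7059 for number 10 against 1, 5360 for 4 against 1, 5583 for 10 against 4 and 2329 for KIX against KI. With them limma called 0 genes for D against V in iPSCs (490 at an unadjusted p under 0.05), as it did with an additive model of number and letter (94), where the planned design gave 4 (74). With the fibroblast score as a covariate the counts were 728 for 10 against 4, 128 and 31 for KIX against KI at numbers 1 and 10, and 320 and 1023 for the change of that difference from 1 to 4 and from 4 to 10. The prefix as a replicate block gave 1906 genes for 4 against 1, where no pairing by prefix was taken, and moved no other count of genes by over 1.5 times. For D against V, where the prefix pairs the libraries, the block left 2 lists called in iPSCs, 3 at number 1 and 6 for the change between numbers 10 and 1, against 3, 2 and 5 without it. As a block for KIX against KI the letter moved no count by over 1.5 times. Libraries of the same letter deviated together with r from -0.0587 to 0.113 within a number and -0.187 to 0.206 between numbers, so it does not pair them.

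Number means alone gave 2306 genes for 4 against 1 and 2802 for 10 against 4, and library weights gave 860 for the latter. All 16 libraries in every fit gave 2 genes for D against V in iPSCs, 1 at number 1, 1 at number 10 and 2 for the change between numbers 10 and 1. In EBs, D against V gave 6 genes without a filter and 6 with the EB libraries alone, and a pseudocount of 0.1 gave 2 genes for EB minus iPSC. Quantile normalization gave 15 genes for KIX against KI, and it turned the majority of calls from up to down for EB against iPSC (51.7% to 47.5% up), number 10 against 4 (60.6% to 44.9%), KIX against KI at number 4 (57.0% to 47.5%) and its change from 1 to 4 (52.0% to 46.6%), and from down to up for its change from 4 to 10 (40.6% to 51.9%). Median-ratio rescaling turned it to down for EB against iPSC (49.4%) and the change from 1 to 4 (47.8%) and to up for number 10 against 1 (49.2% to 52.4%). Median-ratio rescaling, no trend and a filter on the mean kept every count of genes within 1.5 times. With an estimated correlation, 1 list was called for EB against iPSC, D against V in iPSCs and at number 10, and its change between numbers 10 and 1, and 0 lists in each of the other comparisons. Genes with the longer seed match differed by 0.0185 for D against V at number 1, past the threshold no longer. Against genes of the same UTR length decile, the differences were -0.0162 for 4 against 1, -0.00274 for D against V in iPSCs, 0.00804 at number 1 and -0.00678 in EBs, no longer past it.

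Leaving out each library in turn gave 10260 to 11009 genes for EB against iPSC, 1826 to 3991 for number 10 against 1, 318 to 1140 for 4 against 1 and 614 to 1877 for 10 against 4. For D against V it gave 2 to 6 in iPSCs, 0 to 3 at number 1, 0 to 1 at number 4, 1 to 3 at number 10, 2 to 40 in EBs, 3 to 29 for EB minus iPSC and 2 to 5 for 10 minus 1. For KIX against KI it gave 2 to 10 over all libraries, 25 to 436 at number 1, 870 to 3857 at number 4, 503 to 4281 at number 10 and 1946 to 4267 in EBs, with 44 to 2658 for 4 minus 1 and 1861 to 4873 for 10 minus 4. Where a letter or prefix was left with 1 library at a number, that library is assumed to vary like the other groups.

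For the 349 gene changes behind the text, 3326 of the values under other settings kept their direction and side of the threshold, 142 were no longer called, 11 became called and 3 turned. Leaving out a library gave 4270, 364, 10 and 20. The 3 turned values were those of Pou5f1 for number 10 against 1 (-0.0463) and Dcn for 4 against 1 (2.56e-05), both with the fibroblast score as a covariate, and Pou5f1 for D against V in iPSCs (-0.0101 after quantile normalization). Genes that turned when a library was left out were uncalled ones, with ranges of -0.242 to 0.00264 for Dnmt3a and -0.0673 to 0.388 for Dnmt3b in EB against iPSC, -0.126 to 0.0397 for Nanog and -0.0399 to 0.138 for Pou5f1 in 10 against 1, -0.497 to 0.0128 for Nanog in the KIX minus KI change from 4 to 10, and -0.196 to 0.000420 for Pou5f1 in KIX against KI. For D against V in iPSCs they were -0.310 to 0.0526 for Dnmt3a, -0.348 to 0.00937 for Dnmt3b and -0.0548 to 0.0641 for Pou5f1. The depth is unknown, so how far it limits genes with low FPKM or a value of 0 cannot be given.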

Other observations

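The gene groups that open this part were assembled, and their counts made, only after their values were seen, as were the splits that keep pairs of libraries together, while the other splits were planned. No enrichment was tested for these groups. Of 15 genes known to be induced by interferon, all rose from number 1 to 10 (median 1.69) and from 4 to 10 (median 3.74), 12 fell from 1 to 4 (median -1.92), and all were lower in EBs than in iPSCs (median -2.64). In KIX, 3 of them were higher at number 4, 2 lower at number 10 and 6 higher in EBs. Irf7, at 34.2 ± 3.71 FPKM at number 1 and 56.8 ± 11.02 at 4, did not pass there (limma, adjusted p = 0.0815). The fibroblast score moved the same way for 1 to 4 (6.73 ± 0.260 and 6.01 ± 0.0912), for 4 to 10 (6.53 ± 0.310 at 10) and in EBs (2.85 ± 1.27), though not for 1 to 10. Of 13 MHC class I genes and their peptide-loading partners, 8 rose from number 1 to 4, 6 from 4 to 10 (median 0.46), where Tap1 went from 14.5 ± 1.33 to 35.8 ± 10.95 FPKM and H2-K1 from 269 ± 32.8 to 164 ± 58.2, and 13 from 1 to 10. In EBs 12 were lower (median -1.88), and 12 were lower in KIX than in KI at number 10, where the fibroblast score was lower too (6.26 ± 0.00959 and 6.79 ± 0.1295). In KIX 1 was higher at number 4 and 7 were higher in EBs. Of 13 genes known to respond to low oxygen, 1 fell from number 1 to 4 (median -0.58), 3 from 4 to 10 (median -0.56) and 11 from 1 to 10 (median -1.14), and 11 were higher in EBs (median 2.31). In KIX, 2 of them were higher at number 1, 10 were lower at number 4 (median -0.85), 4 were lower at number 10 and 1 was higher in EBs.

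Of 8 tested genes of methionine and betaine metabolism, 6 were higher in KIX and 1 was lower at number 4, with 1 higher at number 1, 3 higher at number 10 and 4 lower in EBs. Of the imprinted genes on chromosome 12, Meg3 (-0.61), Rian (-0.65) and Mirg (-0.75) were lower in KIX at number 4, Dio3 (1.92) was higher, and Dlk1 (-0.15, adjusted p = 0.419) did not pass. No biological explanation of these groups was tested.

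Other splits of the same libraries were used to ask whether chance can be excluded. Since D and V libraries of the same prefix and number deviate together, the splits that keep these pairs together were also counted. EB against iPSC called 10664 genes with plain means, and no other of 100 splits called as many (1 of 100, highest other 7425), nor did any other of the 28 splits that keep pairs together (highest other 1126). That share lies under the 0.05 set for it, so chance is unlikely, but 28 splits cannot show a share far below 0.05. Of 35 splits with number means alone the real one called most for number 10 against 1 (4735 genes, 1 of 35, highest other 1), for 4 against 1 (2306, highest other 205) and for 10 against 4 (2802, highest other 206). Among the 3 splits that keep pairs together the highest others were 0, 205 and 206, and 3 splits are too few for a share under 0.05. For KIX against KI with number and EB means, where the letters share a mean and 167 genes were called in place of 9, 2 of 100 splits called as many (highest other 231), but of the 32 fitted splits that keep pairs together 18 did (highest other 3107), so chance cannot be excluded. That points to a structure of the samples by prefix and number. For D against V with number means the real split called 0 genes in limma in place of 4, with 94 at an unadjusted p under 0.05 (100 of 100 splits called at least as many), which decides nothing. The 9 splits that part all 6 pairs, as it does, called at most 1 gene. Both splits with the highest other count of 1036 kept those pairs together and set KIX against KI at number 4.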
